A study of Rattus norvegicus with 10 samples.

How the data were processed

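RNA from the neurointermediate lobe of the pituitary was hybridised to 10 Affymetrix Rat Genome 230 arrays of version 2.0, 5 from rats dehydrated for 3 days and 5 from control rats, male Sprague Dawley animals of 10 to 12 weeks. Each array carried a separate pool of 5 animals, per the labels, so the spread between arrays is the spread between pools, and p-values refer to it. The labels give no replicate numbers, batch or pairing; arrays were numbered within each group in deposition order, as names alone. RNA was amplified with a commercial in vitro transcription kit, per the labels' protocols, and 500 ng of total RNA is stated for 1 array. The series' design text names another tissue than the title and the sample labels, and groups and tissue were taken from the sample labels.

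The deposited table holds 1 intensity per probe set and array on a linear scale. GCOS 1.2, the Affymetrix array software, is named in the submitters' processing notes, while its algorithm, settings and scaling are not stated. The values show that the authors had scaled every array to the same level: the mean after trimming 2% of probe sets at each end was about 100 on all 10 arrays, within the 5% tolerance set beforehand, and no further scaling was applied. Detection calls and background values were not used here, so that signal over background is unknown for single probe sets. No 2 columns were identical, and every sample column was used. Because each array was scaled to a common mean, changes are relative to the average of all probe sets.

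Of 31099 probe sets, 57 hybridisation and quality controls were left out of the tests. Of the other 31042, 20826 had 1 gene symbol in the platform annotation, 436 had several and 9780 had none. Symbols were compared with the RefSeq gene table of assembly GRCr8 through the gene ID, which changed 0 of them, and no coordinates were used because the files name no genome build. Values were transformed as log2(signal + 5), the pseudocount being 0.05 of the trimmed mean, which understates the change of dim genes. The 60% of probe sets with the highest mean log2 value over all arrays were kept, 18625 in number, a filter that does not look at the groups. Of these 13800 had 1 symbol and stood for 10593 genes. A gene was represented by its kept probe set with the highest mean. Probe sets with several symbols were named for none.

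Dehydrated and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided) with Benjamini-Hochberg adjustment, and a probe set was called at an adjusted p under 0.05. Log2 changes are dehydrated minus control with their moderated standard errors. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 22 lists with at least 5 measured genes. In all 24 lists were fixed, 9 of cell type markers and 15 of pathways, and members were adjusted over all probe sets and also over the list alone. RNA integrity was measured on each array as the mean of the log2 ratios of the 3' to the 5' probe sets of GAPDH and beta-actin, with the same pseudocount. Single measures were compared between groups with an exact permutation test over the 252 ways to choose 5 of 10 arrays, whose smallest two-sided p is 0.00794. Correlations with each group's mean taken off, added after the data were seen, used all 14400 orders of the arrays within the groups. Correlations over all arrays used 100000 resamples in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

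The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest increases and the 12 largest decreases among called genes whose groups did not overlap, then Avp, Oxt, Pomc, Pcsk2, Pcsk1, Gal, Pdyn, Gfap, Vim, Gh1, Prl, Fos and Drd2 whatever their result, and for each list up to 4 called members by size or, with none called, the member with the smallest p. Pcsk1 had no kept probe set with 1 symbol and is not analysed here. Other probe sets of a named gene were checked, and none passed in the opposite direction.

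The steps were tested on simulated data with the probe sets' own means and spreads and 5 arrays per group, in which 50 probe sets each were changed by a log2 size of 0.5, 1, 2 or 3. Over 18625 probe sets, 56% were recovered at 0.5, 82% at 1, 88% at 2 and 82% at 3, and 2 of 159 calls (1.26%) fell on unchanged probe sets. None of the unchanged lists was called by camera, and a list whose 26 measured genes were lowered by 0.3 was called (camera adjusted p = 4.85e-21). The simulated probe sets varied independently of each other, so the list results hold only for uncorrelated genes. On the real arrays the estimated correlation within a list reached 0.629, for ribosomal proteins. False list calls under such correlation were not tested.

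Alternatives changed 1 choice at a time: quantile, median and cyclic loess normalization, a pseudocount of 0.5 or 20, a floor of 10, no filter or a 40% filter, no intensity trend, a robust variance model, array weights, the 3' to 5' ratio or the anterior lobe hormone genes as a covariate, each array left out, a test of unequal variances for each probe set, a 2-fold limit, an adjusted p under 0.01, the mean of a gene's probe sets, the estimated correlation and fry. Leaving out the 2 arrays of highest and lowest 3' to 5' ratio, or dehydrated 5 and control 1, was added after the data were seen. These 2 arrays were also placed on the probe sets called from the other 8, and on the genes fixed by name among them, as the signed mean log2 value between the group means.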

Results

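Gene expression was measured in the neurointermediate lobe of the pituitary of male Sprague Dawley rats that had been dehydrated for 3 days and of control rats. This dissection holds the neural lobe, where the axons of hypothalamic vasopressin and oxytocin neurons end among glial pituicytes, and the intermediate lobe, which is made up mostly of melanotrophs. Each group had 5 arrays, and each array carried RNA from a separate pool of 5 animals. The series' design text names the supraoptic nucleus as the tissue, whereas its title and every sample label name the neurointermediate lobe, and the sample labels were followed here. The 10 arrays correlated with each other at r = 0.940 to 0.981 across probe sets. Their median signals were 36.6 ± 1.33 (SD, n = 5) in the dehydrated group and 37.7 ± 1.29 (SD, n = 5) in the control group. The number of arrays limits the precision of every comparison. The mean log2 ratio of the 3' to the 5' signals of the GAPDH and beta-actin controls, a measure of RNA integrity that increases as RNA is shortened, was 2.15 ± 0.38 in the dehydrated group and 1.78 ± 0.48 in the control group (SD, n = 5, exact two-sided permutation p = 0.214). The mean log2 signal of anterior lobe hormone genes, a measure of carry-over from the neighbouring lobe, was 8.70 ± 0.43 and 8.51 ± 0.64, respectively (SD, n = 5, exact two-sided permutation p = 0.587).

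The comparison of dehydrated with control lobes asked which transcripts differed after water deprivation. Avp, which encodes vasopressin (Entrez Gene 24221), rose from a signal of 812 ± 75.5 in the control group to 2140 ± 355 in the dehydrated group (SD, n = 5), a 2.60-fold increase (log2 change 1.38 ± 0.11 SE, limma adjusted p = 1.36e-06). Oxt, which encodes oxytocin (Entrez Gene 25504), rose 1.78-fold, from 1122 ± 58.6 to 2002 ± 182 (SD, n = 5; log2 change 0.83 ± 0.07 SE, adjusted p = 6.08e-06). Galp, which encodes galanin-like peptide, a product of pituicytes, had the largest increase of any named gene, 7.76-fold from 24.7 ± 5.60 to 228 ± 53.9 (SD, n = 5; adjusted p = 8.61e-08). Gfap, the intermediate filament of astroglia and pituicytes, rose 5.20-fold from 71.2 ± 21.3 to 395 ± 121 (SD, n = 5; adjusted p = 5.30e-06). In the other direction, Pcsk2, the prohormone convertase that cleaves pro-opiomelanocortin in melanotrophs, fell from 715 ± 107 to 391 ± 106 (SD, n = 5; log2 change -0.88 ± 0.14 SE, adjusted p = 0.00219). For each of these 5 genes, all dehydrated arrays lay on one side of all control arrays.

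**Figure D1:**
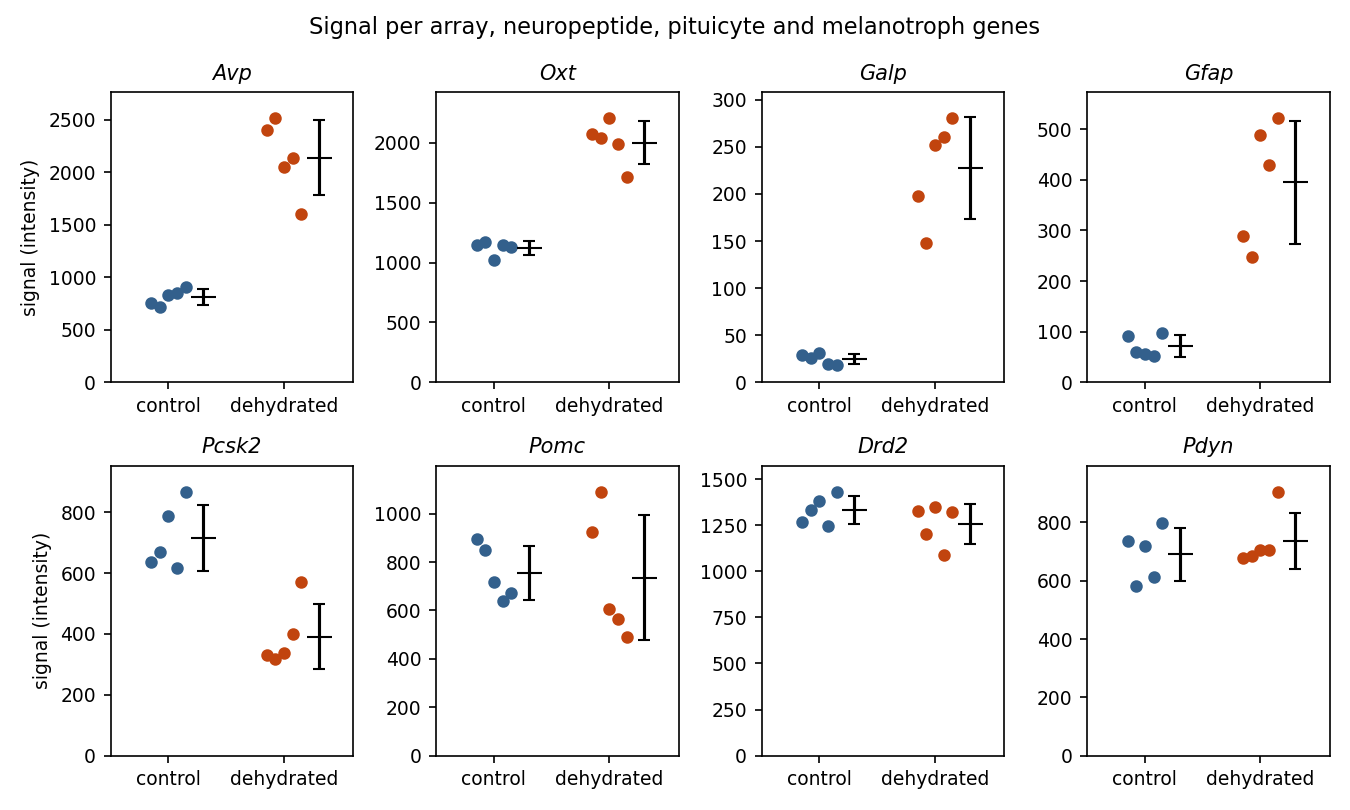
Signal (linear intensity, each axis from 0) of 8 genes on the 5 control and 5 dehydrated arrays. Points are arrays, and the bar beside them is the mean with its SD. Avp, Oxt, Galp and Gfap were higher and Pcsk2 lower on every dehydrated array, while Pomc, Drd2 and Pdyn overlapped between the groups.

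Among the other genes of the 12 largest increases, Msmp, a secreted microseminoprotein, rose by 2.16 on the log2 scale, and Angptl4, a fasting-induced inhibitor of lipoprotein lipase, rose by 2.08. The acute-phase lipocalin Lcn2 rose by 1.92 and the chitinase-like protein Chi3l1 by 1.69. The interferon-induced ubiquitin-like protein Isg15 rose by 1.33, and the transcription factor gene Egr2 by 1.29. Hsd11b1, the enzyme that regenerates active glucocorticoid, rose by 1.26. The calcium-binding protein gene S100a6 and the matrix protein gene Postn each rose by 1.24. Adjusted p for these 9 genes lay between 8.61e-08 and 0.000829.

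Among the named genes the largest decreases were those of Nr4a2 and Nr4a1, orphan nuclear receptors of 1 family. Nr4a2 fell by 1.99 on the log2 scale, from a signal of 339 ± 94.7 to 81.3 ± 23.5 (SD, n = 5, limma adjusted p = 2.20e-05). Nr4a1 fell by 1.89, from 935 ± 170 to 251 ± 56.5 (SD, n = 5, adjusted p = 2.66e-06). Chia, an acidic chitinase, fell by 1.67, opposite to its relative Chi3l1, and Nr4a3, of the same family as Nr4a1, fell by 1.64 (adjusted p = 0.000887). The phosphatase gene Dusp1 fell by 1.33, the small GTPase gene Gem fell by 1.17, Egr1 fell by 0.99, the collagen gene Col2a1 fell by 0.97, the organic cation transporter gene Slc22a3 fell by 0.94, and the proteoglycan gene Spock3 fell by 0.91. Adjusted p for these 7 genes was at most 0.00951. Bcas3 fell by 1.29 on the probe set used, while its second probe set changed by -0.05 (adjusted p = 0.908). Arpp21 fell by 1.25 with an adjusted p of 0.0426, and that call ended under 16 of its alternatives, where adjusted p reached 0.117. These included leaving out dehydrated 1, dehydrated 3 or any one of the 5 control arrays. The call of Egr1 ended with a robust variance model or without an intensity trend (adjusted p up to 0.0531).

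Several genes of the lobe's main cell types did not pass. Pomc, the precursor of the melanotroph hormones, had signals of 735 ± 258 in the dehydrated and 755 ± 111 in the control group (SD, n = 5; log2 change -0.09 ± 0.18 SE, limma adjusted p = 0.837). The dopamine receptor gene Drd2 changed by -0.08 (adjusted p = 0.594), the dynorphin precursor gene Pdyn by 0.09 (adjusted p = 0.685), the galanin gene Gal by 0.34 (adjusted p = 0.232, and 0.0483 without dehydrated 5 and control 1) and Vim, another intermediate filament, by 0.24 (adjusted p = 0.145). Among anterior lobe hormone genes, Gh1 changed by 0.38 (adjusted p = 0.625) and Prl by 0.00 (adjusted p = 0.996). In the dehydrated and control groups the mean signals were 2521 and 2108 for Gh1 and 1381 and 1301 for Prl, above those of Pomc. Pomc had no other kept probe set, and how well the one used reads its transcript was not tested. Its value alone therefore does not show an unchanged share of melanotrophs.

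In all, 458 of 18625 tested probe sets passed an adjusted p of 0.05, 312 higher and 146 lower in the dehydrated group (68.1% higher). They covered 338 genes by the probe set used for each gene, 245 higher and 93 lower. The median log2 change over all tested probe sets was -0.01. Of the 458, 38 changed at least 2-fold, 21 upward and 17 downward. In 373 of the 458 the groups did not overlap; among all tested probe sets 4.59% had no overlap, where chance gives 0.794%. Centring each array on its median gave 451 higher and 113 lower (80.0% higher), beside 312 and 146 as scaled by the authors. The count depended on single arrays: it was 1156 without dehydrated 5, 218 without dehydrated 3, 301 without dehydrated 1, and 290, 288, 299 and 304 without control 2, 3, 4 and 5, respectively. Without dehydrated 5 and control 1 together it was 1398, 667 higher and 731 lower (47.7% higher), with 442 of the 458 among them. On the 8 arrays left, the 3' to 5' ratio was 2.05 to 2.67 in the dehydrated and 1.26 to 1.91 in the control group. With the ratio as a covariate 24 probe sets passed on those 8 arrays. Dehydration and RNA integrity therefore cannot be told apart for this count. On those 1398 probe sets dehydrated 5 lay at 35.4% and control 1 at 40.6% of the way from the control to the dehydrated mean of the other 8 arrays. On the 6 genes fixed by name that were called from those 8 arrays, they lay at 80.4% and 2.95%. Over all 10 arrays, the count with the 3' to 5' ratio as a covariate was 338, of which 290 were among the 458.

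Immediate early genes, which neurons and endocrine cells switch on within minutes of stimulation, had the lowest mean change of the 22 tested lists, -0.40 on the log2 scale. Of 21 measured members, 8 fell, 2 rose and 11 did not pass; adjusted over the list alone, 9 fell and 2 rose. Fos fell by 1.46 on the log2 scale, from a signal of 1049 ± 509 to 345 ± 82.6 (SD, n = 5, limma adjusted p = 0.00862), although the groups overlapped, and its call ended with a robust variance model or without the 2 arrays of extreme 3' to 5' ratio (adjusted p up to 0.0731). The list also contains the 3 Nr4a genes, Dusp1 and Egr1, described above as lower. Egr2 and Dusp6, a phosphatase of the same family as Dusp1 that was named after its value was seen, went the other way, with log2 changes of 1.29 and 0.96. The list was lower as a set (camera adjusted p = 0.00118; adjusted p = 0.0879 with an estimated correlation).

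**Figure D2:**
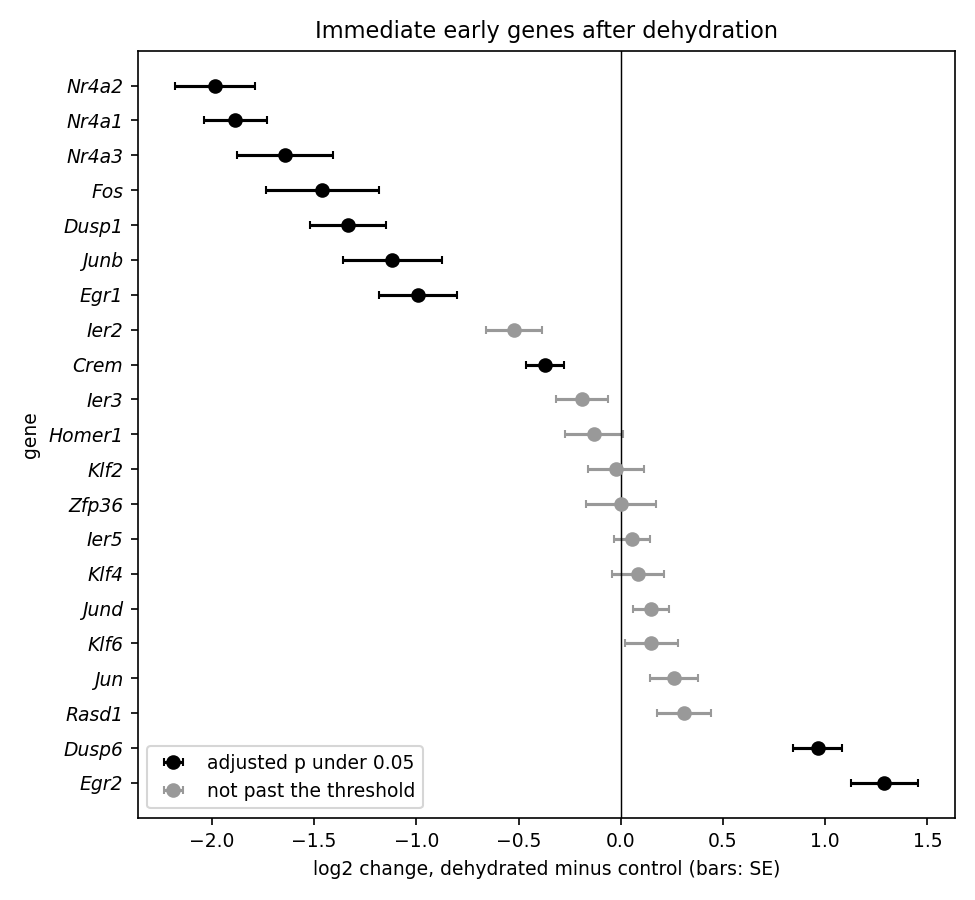
Log2 change, dehydrated minus control, of the 21 measured immediate early genes, with SE bars (5 arrays per group). Black points passed an adjusted p of 0.05 and grey points did not. Nr4a2 at -1.99 is the lowest and Egr2 at 1.29 the highest.

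Among the markers of the lobe's own cells, 1 of 7 measured melanotroph markers, Pcsk2, fell and none rose; adjusted over the list alone 2 fell (camera adjusted p = 0.0137; adjusted p = 0.0879 with an estimated correlation; 0.0672 without dehydrated 4). Of 17 pituicyte and astroglia markers, 3 rose and none fell, and 5 rose adjusted over the list alone. Besides Gfap these were the transcription factor Lhx2 at 0.39 and the glutamate transporter Slc1a3 at 0.36 (limma adjusted p = 0.00564 and 0.00694), and the call of Slc1a3 ended when the probe sets of a gene were averaged (0.038, adjusted p = 0.903). The pituicyte list was higher (camera adjusted p = 0.0177; adjusted p = 0.138 with an estimated correlation), a call that ended without dehydrated 4 (adjusted p = 0.0712), with quantile or cyclic loess normalization, among the brightest 40% of probe sets or with probe sets averaged (adjusted p up to 0.252). Of 8 hypothalamic neuropeptide transcripts, Avp and Oxt rose and none fell; adjusted over the list alone 3 rose (camera adjusted p = 0.00118; adjusted p = 0.0734 with an estimated correlation), and without the filter on dim probe sets its adjusted p was 0.115.

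Of 13 endothelial and pericyte markers, 4 rose and none fell, and 7 rose adjusted over the list alone. The vascular endothelial growth factor receptor genes Flt1 and Kdr rose by 0.90 and 0.63 on the log2 scale, the pericyte gene Rgs5 by 0.72 and the endothelial sialomucin Emcn by 0.51 (limma adjusted p at most 0.0151). The call of Flt1 ended without dehydrated 3 (adjusted p = 0.0589) and without the 2 arrays of extreme 3' to 5' ratio (adjusted p = 0.0729). The list was higher as a set (camera adjusted p = 0.000338; adjusted p = 0.104 with an estimated correlation). Of 14 fibroblast and meningeal markers, 4 rose and none fell; adjusted over the list alone 6 rose and 1 fell. They were Postn, the mineralization inhibitor Mgp at 0.99, and the proteoglycans Lum at 0.55 and Dcn at 0.43, the last of which did not pass without an intensity trend or without the 2 arrays of extreme ratio (adjusted p up to 0.0550). This set held with both correlations (camera adjusted p = 0.000520 and 0.0321). Of 36 extracellular matrix genes, 11 rose and none fell, and 16 rose adjusted over the list alone. Examples were the collagen cross-linking enzyme Lox at 0.83, the laminin chain Lamb1 at 0.77, the collagen chain Col6a3 at 0.75 and the proteoglycan Vcan at 0.71, whose call ended without dehydrated 3 or control 2 (adjusted p up to 0.0626). The set was higher (camera adjusted p = 2.13e-07; adjusted p = 0.104 with an estimated correlation), and it shares 6 genes with the fibroblast list.

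Genes of sterol synthesis were lower as a set. Of 26 measured members, 5 fell and none rose, 24 had a negative change, and 9 fell adjusted over the list alone. Idi1, an isoprenoid pathway enzyme, fell by 0.77 on the log2 scale. Sqle, which makes squalene epoxide, and Fdps, which makes farnesyl diphosphate, also fell, with log2 changes of -0.49 and -0.48 (limma adjusted p at most 0.00548 for the 3). Srebf2, the transcription factor that drives this pathway, fell by 0.60 (adjusted p = 0.0270). Its call ended without dehydrated 1 or 3 or without control 1, 2, 3 or 5 (adjusted p up to 0.0739). It also ended with the 3' to 5' ratio as a covariate, among other settings (adjusted p up to 0.0814). The set held with both correlations (camera adjusted p = 1.13e-08 and 0.0154).

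Genes that respond to glucocorticoids and fasting rose, 7 of 26 measured, with 1 that fell; adjusted over the list alone 9 rose and 1 fell. The members that rose included Angptl4, Hsd11b1 and Pdk4, the kinase that restrains pyruvate oxidation, which rose by 0.73 on the log2 scale (limma adjusted p = 0.00208), and the member that fell was Dusp1. The other 18 did not pass over all probe sets, among them Tsc22d3 at -0.03, Klf9 at 0.08 and Per1 at 0.02. The set held with both correlations (camera adjusted p = 0.000178 and 0.0321). Of 14 osmotic stress genes, 4 rose and none fell; adjusted over the list alone 4 rose and 1 fell. The 4 were the small heat shock protein gene Hspb1 at 0.65, the inositol transporter gene Slc5a3 at 0.63, the kinase gene Sgk1 at 0.54 and the chloride cotransporter gene Slc12a2 at 0.54. Over all probe sets the other 10 did not pass, among them Nfat5 at 0.06 and Akr1b1 at -0.02. Sgk1 is also in the glucocorticoid and fasting list. The call of Slc5a3 (adjusted p = 0.0319) ended without dehydrated 1, 2 or 3 or without control 1, 3 or 5 (adjusted p up to 0.110), and that of Sgk1 ended without an intensity trend (adjusted p = 0.0583). The osmotic list was higher (camera adjusted p = 0.0137; adjusted p = 0.0866 with an estimated correlation), a call that ended without dehydrated 5 (adjusted p = 0.0570), without dehydrated 5 and control 1 together, with quantile or cyclic loess normalization or with probe sets averaged (adjusted p up to 0.108).

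Interferon-responsive genes were higher, with 8 of 23 measured members that rose, none that fell, and 10 that rose adjusted over the list alone. Besides Isg15, the antiviral membrane protein gene Ifitm3 rose by 0.60 on the log2 scale (limma adjusted p = 0.000733). Oas1a at 0.71 and Ifi27l2b at 0.60 passed (adjusted p = 0.0463 and 0.0264), but the call of Oas1a ended without dehydrated 2, 3 or 4 or control 1, 2, 4 or 5, and that of Ifi27l2b without dehydrated 1, 2 or 3 or control 1, 2 or 5 (adjusted p up to 0.133). The set was higher (camera adjusted p = 1.13e-08; adjusted p = 0.0879 with an estimated correlation).

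Of 45 ribosomal protein genes, 10 rose and none fell, and 36 rose adjusted over the list alone. Rps28 rose by 0.50 on the log2 scale, Rpl24 by 0.49, Rps9 by 0.46 and Rpl35a by 0.46 (limma adjusted p = 0.00381, 0.0145, 0.0127 and 0.0408). Without dehydrated 3 the calls of Rpl24 and Rps9 ended (adjusted p = 0.0511), and that of Rpl35a ended without any one of 8 arrays, all except dehydrated 4 and 5 (adjusted p up to 0.117). With the 3' to 5' ratio as a covariate the change of Rpl35a was 0.30, and its call ended (limma adjusted p = 0.0912). The set was higher (camera adjusted p = 3.62e-15; adjusted p = 0.139 with an estimated correlation). Its mean change of 0.26 was 0.059 with quantile (adjusted p = 0.0186) and 0.14 with cyclic loess normalization (adjusted p = 7.71e-09). Quantile normalization also lowered the changes of Rps28, Rpl24 and Rps9 to 0.30, 0.30 and 0.28, and that of Rpl35a to 0.19, which did not pass (adjusted p = 0.173). Of 51 oxidative phosphorylation genes, 5 rose and none fell, and 15 rose adjusted over the list alone. Uqcrq rose by 0.47, Ndufb2 by 0.37, Ndufa2 by 0.30 and Ndufb5 by 0.29 (adjusted p = 0.0230 to 0.0301). Each of these 4 calls ended with the 3' to 5' ratio as a covariate and without dehydrated 1 or 3 or control 2, 3 or 5, among other settings (adjusted p up to 0.132). The set was higher (camera adjusted p = 2.13e-07; adjusted p = 0.0953 with an estimated correlation), and its mean change of 0.14 was 0.077 with quantile or cyclic loess normalization (adjusted p = 0.00186 and 0.00289). Both lists were set against the RNA integrity measure: across the 10 arrays the list mean correlated with the 3' to 5' ratio at r = 0.716 for ribosomal proteins (permutation p = 0.0220, adjusted over 3 relations p = 0.0640; rho = 0.794, permutation p = 0.00868, adjusted p = 0.0260). For oxidative phosphorylation it was r = 0.657 (permutation p = 0.0427, adjusted p = 0.0640; rho = 0.673, permutation p = 0.0386, adjusted p = 0.0578). Without the 2 arrays farthest from the median ratio, dehydrated 2 and control 5, r was 0.591 and 0.556 and did not pass over the 8 arrays left (permutation p = 0.132 and 0.153). The third relation, that of the immediate early genes, had r = -0.51 (permutation p = 0.130, adjusted p = 0.130; rho = -0.62, permutation p = 0.0614, adjusted p = 0.0614). Without the same 2 arrays its r was -0.11 (permutation p = 0.792). With each group's mean taken off, r was 0.644 for ribosomal proteins (exact permutation p = 0.0167, adjusted p = 0.0502; rho = 0.776, exact p = 0.00424, adjusted p = 0.0127). It was 0.590 for oxidative phosphorylation (exact permutation p = 0.0871, adjusted p = 0.131; rho = 0.729, exact p = 0.0299, adjusted p = 0.0448) and -0.31 for the immediate early genes (exact permutation p = 0.498, adjusted p = 0.498; rho = -0.43, exact p = 0.258, adjusted p = 0.258). Without dehydrated 2 and control 5 these values of r were 0.650, 0.702 and 0.075, respectively.

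**Figure D3:**
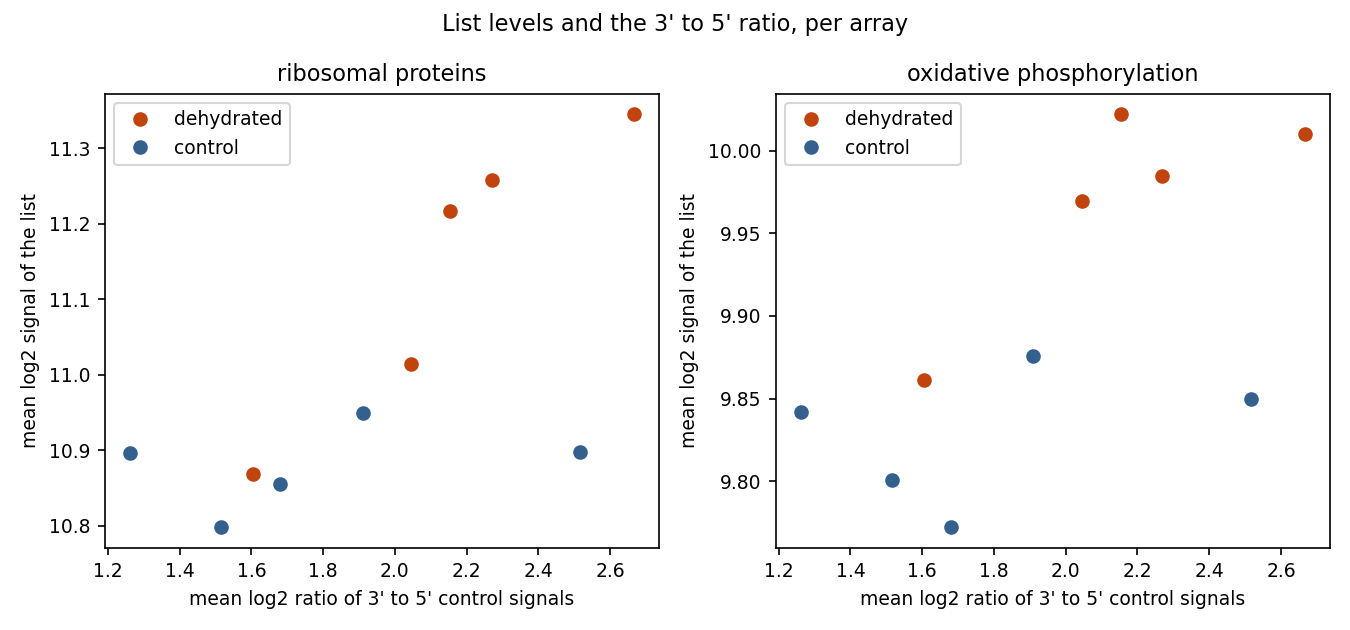
Mean log2 signal of the ribosomal protein genes (left) and oxidative phosphorylation genes (right) against the mean log2 ratio of 3' to 5' control signals, 1 point per array. The dehydrated arrays span ratios of 1.61 to 2.67 and the control arrays 1.26 to 2.52.

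Prohormone processing and granule genes were lower, with 2 of 19 measured members that fell, none that rose, and 5 that fell adjusted over the list alone (camera adjusted p = 0.00400; adjusted p = 0.0734 with an estimated correlation). Besides Pcsk2, the granule membrane protein gene Ptprn2 fell by 0.41 on the log2 scale (limma adjusted p = 0.0264), a call that ended without dehydrated 1, 2 or 3 or control 3 or 4 (adjusted p up to 0.0855). Of 12 dopamine and GABA signalling genes, 1 fell, the phosphatase inhibitor gene Ppp1r1b at -0.54 (adjusted p = 0.0113), and 2 fell adjusted over the list alone. That list was lower (camera adjusted p = 0.0196; adjusted p = 0.236 with an estimated correlation), and its call ended without dehydrated 4, dehydrated 5 or control 5 (adjusted p up to 0.127). It also ended under both other filters on dim probe sets (adjusted p up to 0.178), without the 2 arrays of extreme ratio (0.0877), without dehydrated 5 and control 1 together (0.0865) and with fry (0.0960). Of 28 unfolded protein response genes, the pseudokinase gene Trib3 rose by 0.65 and the disulfide isomerase gene Pdia3 fell by 0.32 (adjusted p = 0.0308 and 0.0162); adjusted over the list alone 2 rose and 4 fell. The call of Trib3 ended without dehydrated 1, 2 or 3 or control 4 or 5, and that of Pdia3 without dehydrated 3 or control 4 (adjusted p up to 0.104). With the probe sets of Pdia3 averaged, its change was -0.14 (adjusted p = 0.334). The list was lower (camera adjusted p = 0.0250; adjusted p = 0.0924 with an estimated correlation), and its call ended without dehydrated 4 or control 5 (adjusted p up to 0.0721). Of 32 cell cycle genes, Ccnd1, a cyclin of the early cell cycle, rose by 0.47 and the tubulin-binding protein gene Stmn1 by 0.40 (adjusted p = 0.0204 and 0.00504), and 4 rose adjusted over the list alone. The cell cycle list was higher (camera adjusted p = 0.00486; adjusted p = 0.0953 with an estimated correlation), while the call of Ccnd1 ended without dehydrated 1 or 3 or control 4 or 5 (adjusted p up to 0.0768). With the probe sets of Ccnd1 averaged, its change was 0.20 (adjusted p = 0.262).

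The remaining 5 tested lists did not pass as sets. Of 7 anterior lobe genes, Fshb, the follicle-stimulating hormone subunit, fell by 0.86 on the log2 scale (limma adjusted p = 0.00507), as did its second probe set (-0.95, adjusted p = 0.00882), and none rose; adjusted over the list alone 2 fell. The mean and median of that list were positive, at 0.10 and 0.26, while its test leaned downward (camera adjusted p = 0.706). Of 19 macrophage and microglia genes, Aif1 rose by 0.42 (adjusted p = 0.0375) and none fell, and adjusted over the list alone 7 rose and 2 fell (camera adjusted p = 0.391, 0.0397 without dehydrated 2 and 0.0426 without the 2 arrays of extreme ratio). The call of Aif1 ended without dehydrated 1, 3 or 4 or control 2, 3 or 5 (adjusted p up to 0.114). Of 19 synaptic vesicle genes, Syt4 fell by 0.29 (adjusted p = 0.0235), also the 1 that fell adjusted over the list alone (camera adjusted p = 0.152, and 0.0146 without control 2), and its call ended without dehydrated 3 or control 1, 3 or 5 (adjusted p up to 0.0864) and with its probe sets averaged (-0.61, adjusted p = 0.0515). Of 27 glycolysis and hypoxia genes, the growth factor gene Vegfa rose by 0.45 and Tpi1 and Ankrd37 fell, with log2 changes of -0.42 and -0.40 (adjusted p = 0.0196, 0.0459 and 0.0408); 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.994). The calls of Tpi1 and Ankrd37 ended without any one of 8 arrays, all except dehydrated 4 and 5, and that of Vegfa without dehydrated 3 or control 4 or 5 (adjusted p up to 0.133). Of 18 circadian clock genes, Hlf rose by 0.44 (adjusted p = 0.00443), also the 1 that rose adjusted over the list alone (camera adjusted p = 0.292), and its call ended when its probe sets were averaged (0.24, adjusted p = 0.0634). Of 2 lists with too few measured genes for a test, the 2 red blood cell genes included Hbb at 0.24 (adjusted p = 0.191), and 1 of them rose adjusted over the list alone. Among the 4 oligodendrocyte and Schwann cell genes, the myelin gene Pmp22 rose by 0.42 (adjusted p = 0.00512), 2 rose adjusted over the list alone, and the call of Pmp22 ended when its probe sets were averaged (0.26, adjusted p = 0.0515).

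In all, 17 of 22 tested lists passed with the preset correlation, 11 higher and 6 lower. With an estimated correlation 3 passed, those of fibroblasts and meninges, of glucocorticoid and fasting responsive genes, and of cholesterol and sterol synthesis. A directional rotation test of each list by itself (fry) passed 16 lists, and its test for change in either direction passed 22; neither compares a list with other genes.

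**Figure D4:**
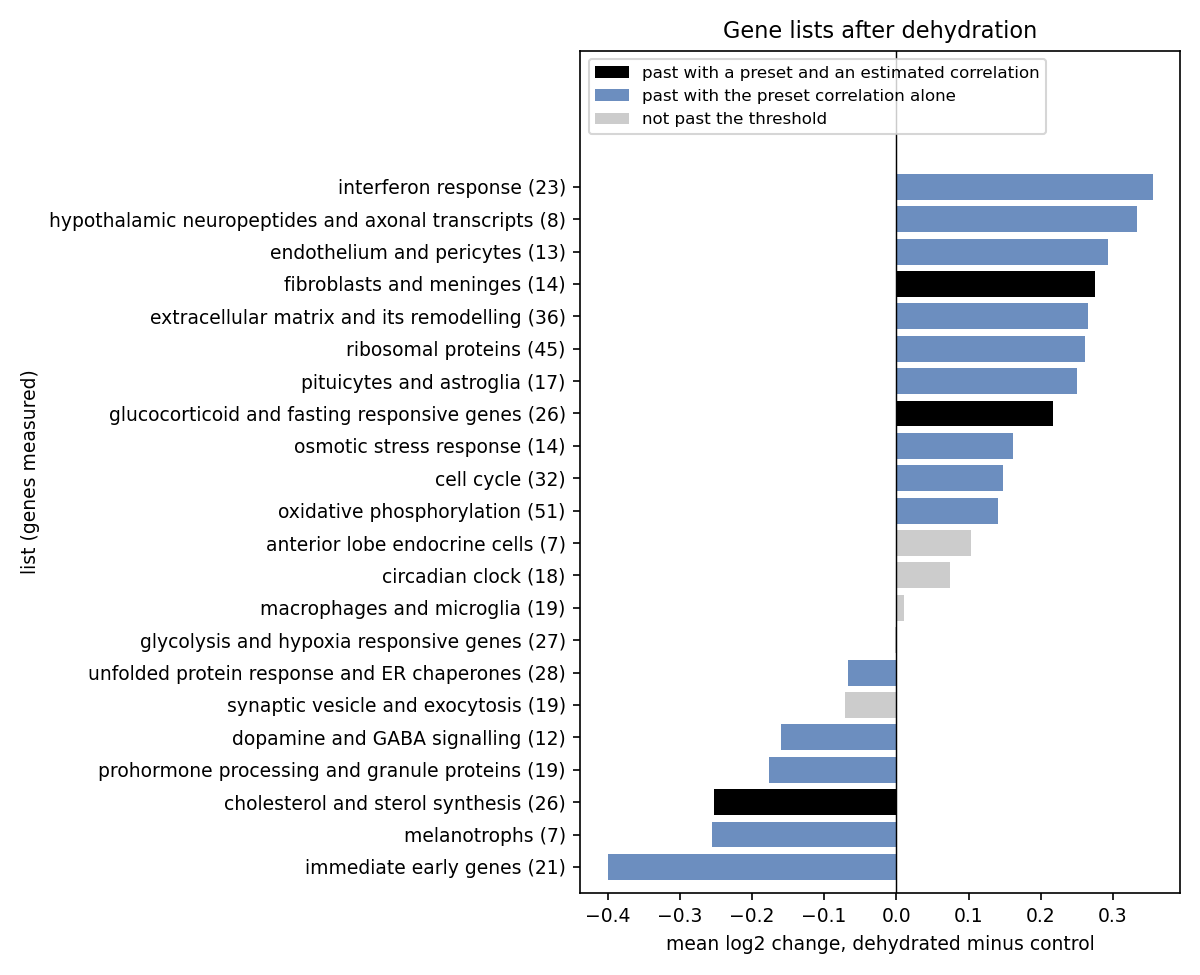
Mean log2 change, dehydrated minus control, of the measured genes of the 22 tested lists, with the number of genes measured in brackets. Black bars passed with both a preset and an estimated correlation, blue bars with the preset correlation alone, and grey bars with neither. The largest mean is 0.35 for interferon response and the lowest is -0.40 for immediate early genes.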

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

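The tests of tissue shares, of an exchange of labels and of the mean of all 21 immediate early genes in this part were chosen after the results were seen. The other tests of the 3' to 5' ratio and those of other splits were set before, but some of their genes were taken from the results. Galp was named for the size of its increase, and the immediate early genes averaged in the planned test were those that fell.

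Across 210 groups of 5 arrays checked, 11 had 1 array whose gap to the nearest of the others exceeded 0.71 of the group's range, or 5.24%, where chance flags about 5%. The gaps were computed on log2 values, while the gene signals below are on the linear scale. Control 3 was the distant array in 3 of the 11. It was high for Isg15 in the control group, at a signal of 184 against 115 to 129 (gap 0.760 of the range), and low for Oxt, at 1021 against 1128 to 1173 (0.713). It was also high for the mean log2 signal of the interferon list, at 7.90 against 7.50 to 7.61 (0.733), and among the dehydrated arrays that list stood highest in dehydrated 3, at 8.21 against 7.89 to 7.95 (0.798). Dehydrated 5 was low for Msmp, at 377 against 468 to 502 (0.759), and high for Pdyn, at 904 against 677 to 704 (0.866). Control 4 was low for Gem, at 290 against 557 to 683 (0.762), and high for Sgk1, at 324 against 286 to 291 (0.851). Control 1 was low for Rgs5, at 93.3 against 113 to 120 (0.748). Dehydrated 4 was low for Hspb1, at 383 against 483 to 521 (0.754). Control 2 was low for the mean log2 signal of the synaptic vesicle list, at 7.04 against 7.26 to 7.30 (0.857).

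The number of changed probe sets was set against 100 splits of the 10 arrays into 5 and 5, drawn from 126 with the real one included. The real split gave 458, and 2 of the 100 splits gave as many, the real one being 1 of them. This is under the limit of 5 in 100, so chance alone is unlikely but not excluded. The highest of the other splits gave 652, with dehydrated 5 and control 1 exchanged, and 96 of the other splits gave 0. That split had the largest difference in the 3' to 5' ratio of all those drawn (0.74 on the log2 scale). With the ratio as a covariate the real split gave 338 and that split 0. In that split the ratio was 2.05 to 2.67 in 1 part and 1.26 to 1.91 in the other. Ratio and grouping can hardly be separated there, so the contrast of 338 and 0 does not decide on an exchange. On the 1398 probe sets called from the other 8 arrays, dehydrated 5 lay at 35.4% and control 1 at 40.6% of the way from the control to the dehydrated mean. With each of the 4 arrays of the other group left out in turn in place of its partner, dehydrated 5 lay at 41.8% to 55.6% and control 1 at 12.1% to 18.3%. On the 24 called from those 8 arrays with the ratio as a covariate, they lay at 102% and 8.82%. The ratio separated the groups of those 8 arrays over the same ranges, so no conclusion is drawn from this placement. The first placement left an exchange of these 2 labels undecided, and a further test was then made on the genes fixed by name that were called from the other 8 arrays (Avp, Oxt, Gfap, Pcsk2, Fos and Gal). Over these 6, dehydrated 5 lay at 80.4% and control 1 at 2.95%, against SDs of 9.19 and 12.9 for the other arrays of each group placed in the same way, which argues against an exchange. Avp was 1603 in dehydrated 5 and 758 in control 1, while the other controls lay between 717 and 910, but Gal alone placed them the other way, at 33.0% and 89.1%, and Pcsk2 placed dehydrated 5 at 32.4%. Why dehydrated 5 lay between the groups on the 1398 probe sets was not settled.

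Gfap, Galp, Avp and Oxt were higher and Pcsk2 was lower on every dehydrated array. A larger share of neural lobe in the dehydrated dissections would raise all pituicyte markers, but those other than Gfap changed by a mean of 0.12 (95% interval 0.03 to 0.21), with an upper bound below 0.5 of the Oxt change of 0.83. A smaller share of melanotrophs would lower their other markers, but these changed by -0.15 (95% interval -0.32 to 0.02), with a lower bound above 0.5 of the Pcsk2 change of -0.88. With the 3' to 5' ratio as a covariate 98.9% of the mean change of the 5 genes, with the sign of Pcsk2 turned, was left (1.67, 95% interval 1.49 to 1.84). Galp was picked for its large increase, which enlarges that mean. Avp, Oxt, Gfap and Pcsk2 were fixed by name. Each of them kept its call in all alternatives, that ratio as a covariate among them (limma adjusted p up to 0.0212). These data argue against each of these explanations as the whole cause, for RNA integrity as far as the ratio measures it. A response to dehydration is a hypothesis that remains, and these data do not show in which cells it took place. For Avp and Oxt this includes the hypothalamic neurons whose axons end in the lobe. Smaller shifts in tissue share stay open.

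Of 21 measured immediate early genes 8 fell, Egr2 and Dusp6 rose and 11 did not pass (list adjusted p = 0.00118; adjusted p = 0.0879 with an estimated correlation). With the 3' to 5' ratio as a covariate, 93.3% of the mean change of the 8 genes that fell was left (-1.26, 95% interval -1.75 to -0.77, beside -1.35 without it). The mean of all 21 was then -0.37 (95% interval -0.58 to -0.15, beside -0.40). This argues against RNA integrity, as far as the ratio measures it, as the whole cause. The mean change of the melanotroph markers was -0.25 (95% interval -0.41 to -0.10), with a lower bound above 0.5 of the mean change of the 8 genes. Those 8 were picked because they fell, which enlarges their mean, so this comparison cannot decide on a smaller share of melanotrophs. For the mean of all 21 the markers reached 0.5 of the change, and a smaller share stays open. Without Pcsk2 the markers changed by -0.15 (95% interval -0.32 to 0.02), short of 0.5 of that change. Lower stimulation of the lobe's cells in dehydrated animals may account for the change, as may handling or the time between killing and dissection, which the labels do not give. These 2 were not tested.

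Of 45 ribosomal protein genes 10 rose and of 51 oxidative phosphorylation genes 5 rose, and neither list passed with an estimated correlation (adjusted p = 0.139 and 0.0953). With the ratio as a covariate 69.6% of the mean change of the ribosomal protein genes was left (0.18, 95% interval -0.01 to 0.38, beside 0.26 without it), so that lower RNA integrity and an effect of dehydration cannot be told apart for them: most of the change was left, but its interval includes 0. For the oxidative phosphorylation genes 80.7% was left (0.11, 95% interval 0.04 to 0.19, beside 0.14). This argues against RNA integrity, as far as the ratio measures it, as the whole cause of that change as scaled by the authors. The ratio rests on GAPDH and beta-actin alone and may correct too little. With each group's mean taken off, the list still followed it (rho = 0.729, exact permutation p = 0.0299, adjusted p = 0.0448). Quantile normalization gave mean changes of 0.059 and 0.077 and cyclic loess normalization 0.14 and 0.077, respectively, so the scaling of the arrays stays open as a source of part of both changes. An effect of dehydration stays open as a hypothesis, and a part of either change may come from RNA integrity.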

How the results depend on the processing

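The alternatives without the 2 arrays of extreme 3' to 5' ratio and without dehydrated 5 and control 1 were chosen after seeing the data; the others were planned. The 458 called probe sets all kept their direction in every setting that tested them, and their count stayed within 1.5 times under 3 normalizations, other pseudocounts, a floor, other filters, a robust variance model and both covariates. It was 240 without an intensity trend, 730 with array weights, 253 without the 2 extreme arrays, 1398 without dehydrated 5 and control 1, 38 with a 2-fold limit and 173 at an adjusted p under 0.01, these last 2 being stricter by construction. A Welch test per probe set gave 2623 unadjusted and 73 after Benjamini-Hochberg adjustment. The unadjusted count changes both the test and the adjustment, and limma gave 3233 at an unadjusted p under 0.05. Leaving out 1 array gave 218 to 1156. Of 22 lists, 13 to 18 passed, except that 3 passed with an estimated correlation. Of the 74 called genes among 82 named, 44 kept their call in all alternatives and 30 lost it in at least 1, and none reversed. Besides single arrays, the settings that ended the largest numbers of gene calls were those without an intensity trend (25, adjusted p up to 0.132), without the 2 extreme arrays (20, up to 0.192), without a filter (16, up to 0.114) and with the 3' to 5' ratio as covariate (14, up to 0.126). The 14 were Arpp21, Aif1, Ptprn2, Trib3, Slc5a3, Srebf2, Uqcrq, Ndufb2, Ndufa2, Ndufb5, Tpi1, Ankrd37, Ifi27l2b and Rpl35a. Each of these calls also ended without a filter and without an intensity trend. Of 17 called lists, 3 kept their call in all alternatives. The anterior lobe list, not called, passed only without the 2 extreme arrays (adjusted p = 0.0343), where the macrophage list also passed (0.0426).

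Some values that were not called changed sign. Prl changed by -0.10 with quantile and -0.070 with cyclic loess normalization, -0.21 with array weights, -0.34 with the 3' to 5' ratio and -0.22 with anterior lobe genes as covariate, -0.59 without the 2 extreme arrays, and -0.31 to 0.23 on leaving out 1 array. Gh1 was -0.058 without the 2 extreme arrays, Pdyn -0.078 with the mean of its probe sets, and Pomc 0.098 without dehydrated 5 and control 1 and -0.25 to 0.034 on leaving out 1 array. The mean of the glycolysis and hypoxia list was -0.0013 with fry, whose test leaned upward, 0.029 with the brightest 40%, 0.0045 with array weights, 0.026 with the 3' to 5' ratio and 0.0062 with anterior lobe genes as covariate, 0.00022 with the mean of probe sets, 0.029 without the 2 extreme arrays and -0.025 to 0.026 on leaving out 1 array. The anterior lobe list was 0.21 with the brightest 40% and -0.094 to 0.27 on leaving out 1 array, where its test turned upward without control 3 or 4. The cause was not tested for any of these. Signal over background was not used here, so calls on dim probe sets rest on the filter alone.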

Other observations

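Further genes that rose were chosen after their values were seen (SD, n = 5, limma adjusted p). G0s2, an inhibitor of adipose triglyceride lipase, rose by 1.06 on the log2 scale, from a signal of 310 ± 29.3 to 652 ± 82.8 (adjusted p = 6.08e-06). The matrix protein gene Fbln2 rose by 1.02, the collagen gene Col13a1 by 0.94 and Cthrc1, another matrix-associated product, by 0.91. The gap junction gene Gjc1 rose by 1.05 and the imprinted gene Nnat by 1.01. Rtp4, an interferon-induced gene, rose by 1.01, the glutathione peroxidase gene Gpx2 by 1.00, the lipopolysaccharide co-receptor gene Cd14 by 0.95 and the thyroid hormone binding protein gene Crym by 0.92. Adjusted p for these 9 genes was at most 0.00504.

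Among further decreases, also chosen after their values were seen, Nmb, which encodes the peptide neuromedin B, fell by 0.89 on the log2 scale, from 261 ± 46.5 to 138 ± 22.6 (SD, n = 5, limma adjusted p = 0.000981). Lrp8, a receptor of the low-density lipoprotein receptor family, fell by 0.88, Cndp1, a carnosine dipeptidase, fell by 0.90, and Tcim fell by 0.91. The phosphatase gene Ppm1j fell by 0.82 and Tent5a fell by 0.76. The muscle genes Eno3 and Tnnc2 were also lower, with log2 changes of -0.80 and -0.78 (adjusted p = 0.00351 and 0.0172). These values were not examined under the alternatives.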
